A study of Mus musculus with 57 samples.

How the data were processed

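Total RNA sequencing of mouse oocytes, embryos of the preimplantation stages, and embryos of a knockdown and a knockout experiment was analysed from the table the authors deposited. Per the labels, libraries were made with TruSeq Stranded Total RNA or, for small amounts, SMARTer Stranded Total RNA v2 kits; which kit served which sample is not given in the sources used here. The injected embryos received 5 to 10 pL as MII oocytes, with the ASO at 20 uM, or guide RNA at 150 ng/uL and Cas9 mRNA at 100 ng/uL. No injection or dose is listed for the controls of either experiment, so whether they were injected is not known here. The authors named cutadapt 1.18, HISAT2 2.1.0, Cufflinks, StringTie 1.3.4d and Cuffdiff 2.2.1 with genome build GRCm38, without the role or order of each. The deposited values are FPKM (fragments per kilobase of transcript scaled to the mapped fragments of the library), and the authors' denominator and filters are not stated. The table holds 59119 rows and 43 sample columns, 1 per replicate, for the 57 samples. Some samples carry a suffix for an addition and some column names hold words for merging, but which samples a column holds is not stated in the sources used here. The columns of the MT2Mm groups are written with other decimals than the rest. Columns were matched to groups by name. Those of the LncR-3363 experiment carry another short name, and that this name stands for LncR-3363 rests on the structure of the series alone. The words ctrl, KD and 2cell in these names gave the groups. KD columns without 2cell were taken as KD-1cell, by their number. Column names carry tags for MII to L2-cell (MII replicate 1 with zygote replicate 2, zygote replicate 1 with both E2-cell replicates, MII replicate 2 with both L2-cell replicates), which were read as possible batches. Replicate numbers do not pair the samples: correlations of residuals between samples of equal number ran from -0.0889 to 0.093.

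Rows were annotated by Ensembl identifier from release M21, with 54409 of 54446 found, and 53229 with the same version. Loci named XLOC, the form in which Cufflinks names its loci, carry no position in the table. Where a symbol belongs to a family of near-identical genes (Zscan4, Usp17l, Obox, Duxf3, Gm4340), reads may be shared between members. Rows with at least 1 FPKM in as many samples as the smallest group of a fit were tested on log2(FPKM + 0.5) with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3. The 8 stages shared a fit, as did the 3 times and the 4 MT2Mm groups; KD-1cell and Ctrl formed their own, and the single KD-2cell sample entered no test. A row was called at a Benjamini-Hochberg adjusted p under 0.05. The effect of the knockout at Early2c minus that at Late1c was tested as an interaction. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.

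The comparisons, the alternatives and 17 gene lists were fixed before the data were examined. The lists hold imprinted, X-inactivation, snoRNA host, broadly expressed, pluripotency-associated, oocyte, microRNA host and Hox lncRNAs, structural RNAs, 2-cell genes, maternal genes, blastocyst genes, markers of cumulus and granulosa cells, markers of sperm and testis, housekeeping genes, p53 and damage genes, and interferon genes. They come from general knowledge of the field. Each list was counted with p-values adjusted over all rows and again adjusted over the list alone. Lists with at least 5 tested members, and the rows called higher or lower at the 3 first steps of the stage series, were tested as sets with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, two-sided, in the knockdown and knockout comparisons. Of 58 pairs of set and comparison 18 passed camera, 9 upward and 9 downward.

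Genes named in the text follow a rule of the same date: up to 4 members per list, called ones first, then the 8 largest rises and the 8 largest falls among called genes with at least 5 FPKM in the higher group and no overlap of replicates, and up to 2 XLOC loci each way. Not every gene the rule allows is printed. On simulated data with planted changes, limma recovered 46% to 59% of changes of 1 on the log2 scale in the stage series, 88% to 91% in the time series, 88% in the knockdown and 94% to 95% in the 2 knockout comparisons. Of its calls there 2.6% to 9.9% were false.

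Alternatives were pseudocounts of 0.1 and 1 FPKM, no filter, scaling of the columns by the median of ratios, the replicate number as a block, each replicate left out, KD-2cell as an added group of the knockdown fit, and fits of the 2 groups of a contrast alone. After the data were seen, fits on the replicates of a shared tag and a count without rows whose transcripts hold the sequence found in the knockdown were added. Splits of the samples into other groups were counted for comparisons with at least 3 samples a side.

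Also chosen after the data were seen were the searches for shared sequences and the comparison of row classes. For the knockdown, every 8-base sequence was counted in the longest annotated transcript of genes with at least 2 FPKM in Ctrl, in 88 called transcripts with a change below -2 against 6987 with a change above -0.5. The choice was tested by dividing the transcripts at random into 2 equal parts, picking the sequence in 1 part and counting it in the other, 20 times. For the knockout, 20-base sequences were counted in 154 called transcripts with a change below -1 against 7375 with a change above -0.25, with the same divisions, and the rising lncRNAs of 1 part were compared by the sequence chosen in the other. Rows that rise were matched in pairs on their changes from zygote to E2-cell and from E2-cell to L2-cell and on their level. A protein-coding gene could serve in more than 1 pair. Intervals of medians of pairs come from 2000 resamplings at 95%. These intervals, and those of the gaps between gene groups, resample rows and not embryos, and rows are not independent replicates. Depth is unknown, so no counting intervals are given. Raw reads, allele or repeat families and the level of LncR-3363 itself were not analysed here.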

Results

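Total RNA was sequenced, as reads of 150 bases, from mouse oocytes and preimplantation embryos in 57 samples that form 18 groups. A stage series covered the MII oocyte, zygote, early 2-cell (E2-cell), late 2-cell (L2-cell), 4-cell, 8-cell, morula and blastocyst, and a time series covered 14, 17 and 20 hours after fertilization, with 150 to 200 embryos per sample. A knockdown of the long noncoding RNA (lncRNA) LncR-3363 used an antisense oligonucleotide (ASO) injected at 20 uM. A CRISPR knockout of MT2Mm, the long terminal repeat that acts as promoter of the endogenous retrovirus MERVL, was read at the late 1-cell (Late1c) and early 2-cell (Early2c) stage. The deposited table holds 59119 rows in FPKM, of which 54446 are Ensembl genes and 4673 are loci named XLOC, for 43 sample columns: 2 per stage and time, 4 for LncR-3363 KD-1cell, 4 for its control (Ctrl), 1 for KD-2cell and 3 for each of the 4 MT2Mm groups. The columns taken as the LncR-3363 experiment carry another short name in the table. They name control, knockdown and 2-cell, but the link of the short name to LncR-3363 rests on the numbers of samples. Read counts are not given, so the depth of each sample is unknown. Between 10704 and 12892 rows reached 1 FPKM per sample, and FPKM sums ran from 311543 (Late1c knockout replicate 3) to 720832 (L2-cell replicate 2). Small and ribosomal RNA took 15.3% of the FPKM sum in blastocyst replicate 2 and 60.1% in L2-cell replicate 2. Correlations of log2 levels between replicates were between 0.955 (zygote) and 0.993. Levels below are mean FPKM ± SD, with n = 2 in the stage and time series, changes are log2 values of the later or treated group over the other, and p-values are limma's, adjusted over all rows tested.

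From the MII oocyte to the zygote, the question was which RNAs changed around fertilization, before the main activation of the embryonic genome. Khdc3, Nlrp2 and Plat, transcripts of the oocyte, fell: Khdc3 from 42.1 ± 1.1 to 18.8 ± 2.3 (-1.14, adjusted p = 0.0014), Nlrp2 from 78.1 ± 14 to 36.8 ± 3.2 (-1.07, adjusted p = 0.007) and Plat, the tissue plasminogen activator, from 435 ± 3.5 to 198 ± 26 (-1.14, adjusted p = 0.0024). Respiratory chain subunits were among the genes named by the size of their fall, with Ndufa9 from 34.3 ± 7.4 to 5.76 ± 4.8 (-2.71) and Uqcr11 from 34.2 ± 6.7 to 8.81 ± 2.7 (-1.92). The ubiquitin ligase gene March7 fell by 2.69, and XLOC_000547 fell from 20.9 ± 1.0 to 2.71 ± 0.23. The predicted gene Gm15446 rose from 0.927 ± 0.13 to 16.1 ± 3.8 (3.53), the double homeobox gene Duxbl1 rose by 0.84, and XLOC_000034, listed at 0 in the oocyte, reached 20.5 ± 0.22. Of 31 maternal genes 2 rose and 5 fell, or 5 and 8 when adjusted over the list alone. Of 7 structural RNA genes 2 rose (4 adjusted over the list alone), of 47 2-cell genes 1 rose (1 adjusted over the list alone), and of 17 snoRNA host genes 1 fell (1 adjusted over the list alone). Of 3 oocyte lncRNAs limma called 0, with 2 at an unadjusted p under 0.05 and 2 higher when adjusted over the list alone. In all, 740 of 19692 rows were called, 341 higher and 399 lower, or 425 higher and 310 lower with scaling by the median of ratios. This count rests on single libraries: it was 371 without MII replicate 1 and 5008 without zygote replicate 2, and it was 936 (342 higher, 594 lower) with only the replicates that share a tag in the column names. That fit sets 1 sample, MII replicate 1, against 1, zygote replicate 2, and kept 355 of the 740 calls. Mitochondrial RNA took 0.317% and 0.46% of the FPKM sum in those replicates, against 5.56% in MII replicate 2 and 2.75% in zygote replicate 1.

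Between the zygote and the E2-cell embryo, the comparison asked which genes the embryo activates and which maternal RNAs it clears. The 2-cell genes rose almost as a block, 42 of 47 higher and 2 lower (the same numbers adjusted over the list alone), with a median change of 4.70. Zfp352 (ENSMUSG00000070902.5, GRCm38 chromosome 4, 90218820 to 90225702), a zinc finger gene of the 2-cell embryo, was listed at 0 in the zygote and reached 45.3 ± 0.34 (adjusted p = 1.7e-09). Duxf3 (ENSMUSG00000075046.7, chromosome 10, 58229979 to 58232675), the Dux homeobox factor that activates MERVL and 2-cell genes, rose from 0.0786 ± 0.034 to 9.16 ± 0.16 (4.06, adjusted p = 2.5e-09). Spz1 went from a listed 0 to 14.7 ± 0.58, and Gm4340, a gene of a family with near-identical copies among which reads can be shared, went from 0.0235 ± 0.033 to 112 ± 12. XLOC_013418 rose from 0.0633 ± 0.09 to 60.8 ± 9.4 (6.77). Of 31 maternal genes 17 fell and 2 rose (18 and 3 adjusted over the list alone): the egg coat gene Zp1 went from 172 ± 21 to 18.9 ± 2.8 (-3.15), Padi6 from 795 ± 66 to 135 ± 11 (-2.55) and Tle6 from 194 ± 37 to 41.3 ± 0.69 (-2.20). Gm813, a predicted gene, fell from 499 ± 67 to 36.3 ± 2.3 and Cox7c, a respiratory chain subunit, from 22.2 ± 4.1 to 1.03 ± 0.3.

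Noncoding RNAs with known functions moved in both directions at this step. Of 17 snoRNA host genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), among them Snhg8 from 0.553 ± 0.16 to 4.01 ± 0.47 and Zfas1 from 0.575 ± 0.48 to 3.14 ± 0.43, while Snhg6 fell by 1.76. The nuclear speckle RNA Malat1 rose from 0.935 ± 0.12 to 4.65 ± 0.18 (1.85), within a list of 8 broadly expressed lncRNAs of which 2 rose and 2 fell (2 and 2 adjusted over the list alone). Of 12 pluripotency-associated lncRNAs 2 rose and 1 fell (the same adjusted over the list alone): Platr31 went from 0.0203 ± 0.029 to 2.25 ± 0.36, Platr25 rose by 1.76 and Platr14 fell by 0.85. Of 3 imprinted and 5 X-inactivation lncRNAs limma called 0, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, and of 3 microRNA host genes 1 fell (1 adjusted over the list alone). No lncRNA of the Hox clusters passed the filter in any comparison. Of 12 housekeeping genes 4 rose and 7 fell (5 and 7 adjusted over the list alone), with Hprt up by 1.17 and Ubb down from 558 ± 41 to 206 ± 8.0. Blastocyst genes were split, 9 of 25 higher and 4 lower (11 and 5 adjusted over the list alone). In all, 8685 of 19692 rows were called, 3517 higher and 5168 lower. With only the replicates of the shared tag (zygote replicate 1 and both E2-cell replicates) 9578 were called, and scaling moved the log2 changes of rows by a median of 0.154, giving 4685 higher and 4308 lower.

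The E2-cell and L2-cell embryos were compared to follow the main wave of activation. Obox6, a homeobox gene, rose from 1.31 ± 0.094 to 79.8 ± 6.2 (5.47, adjusted p = 5.8e-11) and Pramel7 from 1.24 ± 0.34 to 76.8 ± 6.5. Kcnk6 rose from 0.00972 ± 0.014 to 37.6 ± 4.9, Pdxk from 0.56 ± 0.091 to 84.8 ± 0.97 and Tomm5, a subunit of the mitochondrial import complex, from 0.136 ± 0.19 to 61.3 ± 0.084. Fgf4 and Tead4, a growth factor and a trophectoderm regulator, were listed at 0 in E2-cell embryos and reached 9.97 ± 0.036 and 6.33 ± 1.0. Of 25 blastocyst genes 9 rose and 11 fell (9 and 11 adjusted over the list alone, 8 and 12 with scaling). Duxf3 had already fallen again, from 9.16 ± 0.16 to 0.499 ± 0.05 (-3.27), and 25 of 47 2-cell genes fell while 13 rose (26 and 13 adjusted over the list alone). Maternal genes fell throughout, 27 of 31 with none higher (28 adjusted over the list alone): Obox1 from 531 ± 18 to 24.1 ± 3.2 (-4.44), Ooep from 167 ± 6.2 to 15.2 ± 1.5 and Tcl1 from 683 ± 30 to 63.1 ± 1.9. Rgs2 fell from 139 ± 8.0 to 2.21 ± 0.0084. Snhg15, Snhg1 and 10 further snoRNA host genes rose, 12 of 17 in all (14 adjusted over the list alone), Platr17 rose by 3.68 and Platr30 fell by 3.17. All 3 oocyte lncRNAs fell (3 adjusted over the list alone), C86187 from 831 ± 17 to 207 ± 36. Sesn2, a stress gene that p53 can induce, rose from 3.72 ± 0.71 to 74.4 ± 13, 1 of 2 risers among 10 p53 and damage genes, of which 1 fell (2 and 1 adjusted over the list alone). Both interferon genes tested fell (2 adjusted over the list alone), with Ifit1 from 1.32 ± 0.37 to 0.0267 ± 0.038, and so did the only sperm marker tested, Prm2, from 2.32 ± 0.23 to a listed 0 (1 adjusted over the list alone). XLOC loci were lower more often than higher, 1705 against 611 of 3127, as were annotated lncRNAs (627 against 299 of 1299). In all, 13525 of 19692 rows were called, 6130 higher and 7395 lower, and scaling moved the changes by a median of -0.175, giving 5663 higher and 8414 lower. Every E2-cell column carries 1 tag and every L2-cell column another, so tag and stage cannot be told apart here.

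**Figure D1:**
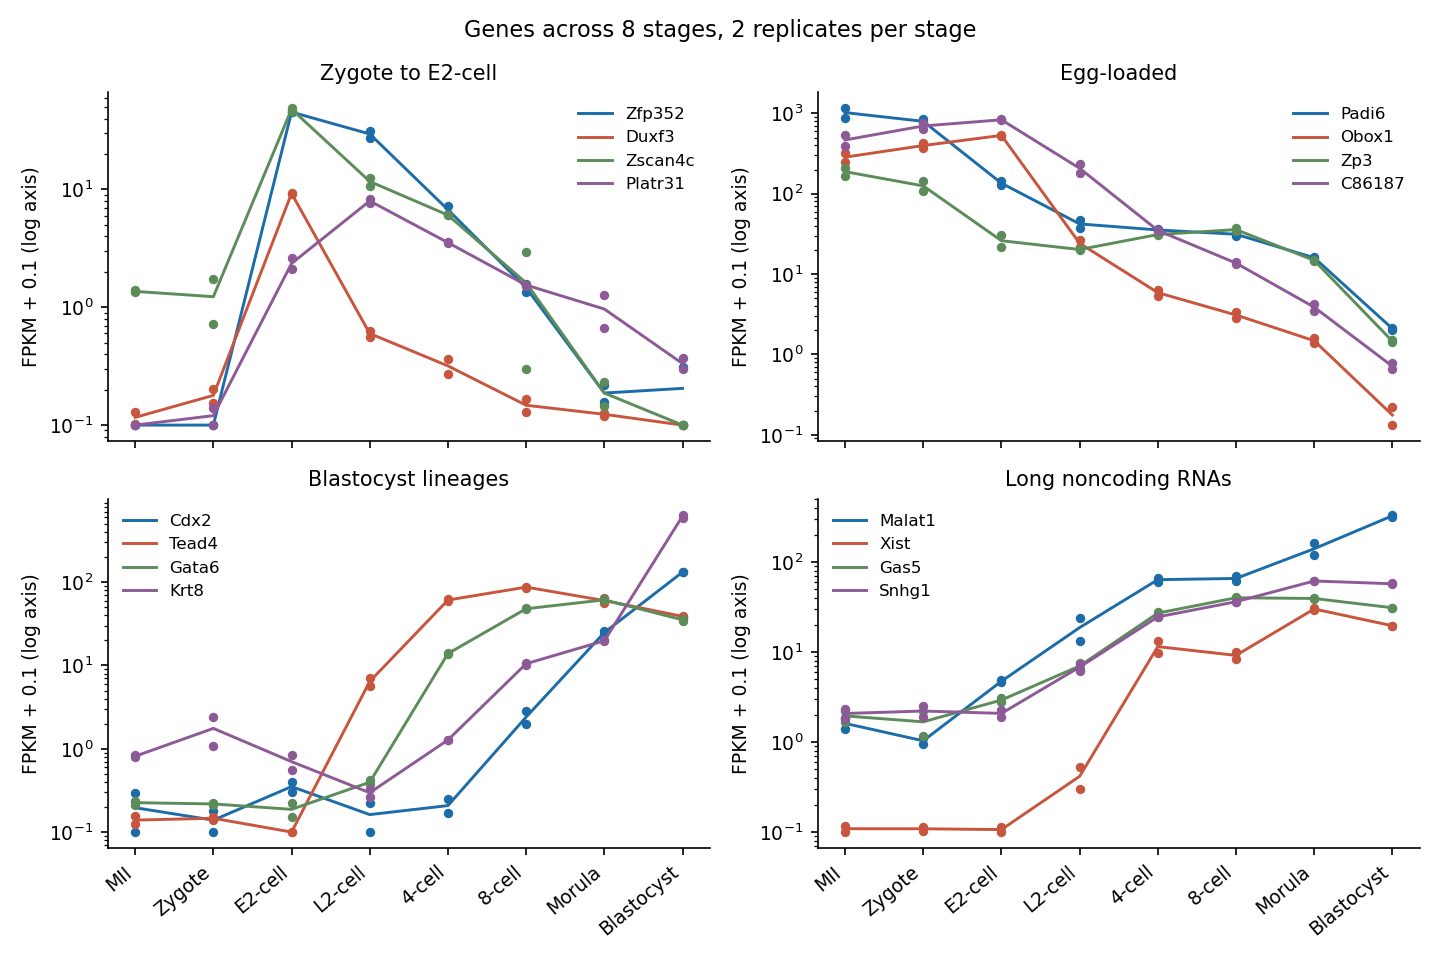
FPKM plus 0.1 on a log axis for 16 named genes over the 8 stages from MII oocyte to blastocyst; lines join the means of 2 replicates and points are the replicates. Duxf3 peaks at 9.16 in the E2-cell embryo, Padi6 falls from 795 in the zygote to 135 in the E2-cell embryo, and Krt8 reaches 620 in the blastocyst.

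From the L2-cell to the 4-cell stage, lineage and X-linked noncoding genes rose. The Nodal co-receptor gene Tdgf1 went from 0.381 ± 0.17 to 48.8 ± 2.3 (5.82, adjusted p = 6e-10), the endoderm factor Gata6 from 0.296 ± 0.034 to 13.8 ± 0.29 and Tead4 from 6.33 ± 1.0 to 60.9 ± 1.5. Blastocyst genes rose in 18 of 25 cases and fell in 1 (19 and 1 adjusted over the list alone). All 5 X-inactivation lncRNAs tested rose (5 adjusted over the list alone), Xist from 0.316 ± 0.16 to 11.4 ± 2.5 (3.87) and Ftx by 0.66. Gas5 rose from 6.91 ± 0.82 to 27.0 ± 0.87, while Rny1 fell from 59.5 ± 29 to 3.21 ± 1.7 with 4 other structural RNA genes of 7 (6 adjusted over the list alone). Maternal transcripts such as Btg4, from 320 ± 46 to 45.1 ± 1.5, fell in 18 of 31 cases and rose in 4 (18 and 4 adjusted over the list alone), with Khdc3 up by 1.84. Of 12 housekeeping genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), Actb by 2.31 and Eef1a1 by 2.48. In all, 11095 rows were called, 5945 higher and 5150 lower. Scaling moved the changes by a median of -0.187 and turned the balance to 4794 higher and 6174 lower.

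At the 8-cell, morula and blastocyst stages genes of the first lineages rose. From the 4-cell to the 8-cell stage Aqp3, a water and glycerol channel gene, went from 10.2 ± 0.86 to 70.3 ± 0.93, the keratin gene Krt18 from 0.797 ± 0.25 to 8.57 ± 0.18 and Gata6 from 13.8 ± 0.29 to 47.9 ± 0.68. At the morula stage the trophectoderm factors Cdx2 (2.31 ± 0.59 to 24.8 ± 1.1, adjusted p = 6.1e-06), Gata3 (0.385 ± 0.24 to 5.75 ± 0.18) and Eomes (1.71) rose. In the blastocyst Krt8 rose from 19.7 ± 0.3 to 620 ± 34, Spp1 from 0.244 ± 0.24 to 65.4 ± 2.9 and Atp1b1, a subunit of the sodium pump, from 3.35 ± 0.26 to 43.9 ± 2.5. Obox6 fell from 231 ± 6.7 in the morula to 4.74 ± 0.016 in the blastocyst, and the transferrin receptor gene Tfrc fell from 229 ± 4.2 to 9.2 ± 0.59. Of 25 blastocyst genes 15, 12 and 15 rose at the 3 steps (16, 14 and 15 adjusted over the list alone) and 2, 2 and 6 fell (2, 2 and 6 adjusted over the list alone); at the last step 13 rose and 9 fell with scaling. Of 47 2-cell genes 36, 21 and 17 fell (38, 28 and 17 adjusted over the list alone) and 1, 1 and 0 rose (1, 1 and 0 adjusted over the list alone). Of 31 maternal genes 13, 24 and 24 fell (15, 25 and 24 adjusted over the list alone) and 1, 1 and 5 rose (1, 1 and 5 adjusted over the list alone). The maternal gene Khdc3 rose by 1.85 at the 8-cell stage and to 105 ± 5.3 in the morula. Xist rose from 9.12 ± 1.3 in the 8-cell embryo to 30.1 ± 1.1 in the morula. Of 3 imprinted lncRNAs 1 rose in the blastocyst, Rian from 0.069 ± 0.0094 to 1.3 ± 0.02, and 1 fell (1 and 1 adjusted over the list alone). The counts were 6885 (2641 higher, 4244 lower), 4111 (1653 and 2458) and 7618 (4402 and 3216). With scaling the first 2 had 2956 higher and 3431 lower, and 1469 and 2464. The first was 4410 without 8-cell replicate 2 and 4515 without 1 of the 2 4-cell columns, whose numbers match no sample; without morula replicate 2, 8-cell replicate 1 or morula replicate 1 the second was 2423, 2545 or 2573. At the blastocyst step scaling moved the changes by a median of -0.141 and gave 3524 higher and 3680 lower there.

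The time series, at 14, 17 and 20 hours after fertilization, asked when embryonic transcripts first appear. The labels used here give no cell number for these embryos. Duxf3 rose from 0.332 ± 0.025 at 14 hours to 2.69 ± 0.53 at 17 hours (1.93, adjusted p = 0.00065) and to 5.79 ± 0.34 at 20 hours (0.99, adjusted p = 0.0063). Of 16 2-cell genes tested 7 rose in the first interval and 5 in the second, with none lower (7 and 6 adjusted over the list alone). Zfp352 went from 0.193 ± 0.036 at 17 hours to 1.34 ± 0.18 at 20 hours and Gm4340 from 0.536 ± 0.11 to 3.61 ± 0.79. Tet3, the dioxygenase that oxidizes methylcytosine in the zygote, fell from 67.6 ± 1.2 to 24.0 ± 0.14 (-1.48, adjusted p = 0.00067) in the first interval, and the methyltransferase gene Kmt2b fell by 1.39. The oocyte linker histone gene H1foo fell from 923 ± 57 to 509 ± 32 and then to 328 ± 4.3. Of 31 maternal genes 12 rose and 12 fell in the first interval (14 and 14 adjusted over the list alone), and 1 rose and 12 fell in the second (1 and 12 adjusted over the list alone). In the first interval Zp1 fell by 0.86 and Zar1 by 0.73, while Oog1 rose by 0.41. Rmrp, the RNA of RNase MRP, rose from 19.7 ± 2.9 to 36.6 ± 2.0 and to 198 ± 22, and Malat1 from 1.94 ± 0.49 at 17 hours to 14.3 ± 0.37 at 20 hours. Gm15446 was high at 17 hours alone among the 3 times, at 15.7 ± 2.3 against 1.27 ± 0.0092 at 14 hours and 1.58 ± 0.094 at 20 hours. Spp1, Krt18, Timp1 and Vim were higher at 20 hours than at 17 hours: Spp1 at 6.33 ± 0.98 against 0.276 ± 0.058, Krt18 at 3.25 ± 0.82 against 0.0584 ± 0.083, Timp1 at 5.54 ± 2.5 against a listed 0 and Vim, 1 of 3 cumulus and granulosa markers tested, at 1.28 ± 0.18 against 0.0707 ± 0.038. Another of these markers fell (1 and 1 adjusted over the list alone). Annotated lncRNAs and XLOC loci rose more often than they fell in the first interval, 211 against 29 of 768 and 450 against 38 of 1650. In the second 202 XLOC loci fell and 18 rose. The names of both columns at 17 hours hold another word (cat) than those at 14 and 20 hours (merge). Whether the columns were handled differently is not stated, so handling and time cannot be told apart in either interval. In all, 4752 of 12834 rows were called in the first interval (2628 higher, 2124 lower) and 2521 in the second (659 and 1862). With scaling they had 2016 higher and 2525 lower, and 975 and 1029. The first count was 2898 with no filter and 2579 or 2828 without the second replicate of 14 or 17 hours; the second was 905 to 1188 when any 1 of the 4 libraries was left out.

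The control embryos of the knockout experiment also spanned the step from 1 cell to 2 cells, with 3 replicates on each side, and set the background for the knockout. The Zscan4 family, 2-cell genes with near-identical copies among which reads can be shared, rose together: Zscan4e from 0.188 ± 0.022 at Late1c to 56.5 ± 1.1 at Early2c (6.37, adjusted p = 7.3e-14) and Zscan4c from 1.33 ± 0.027 to 67.9 ± 0.81. Of 46 2-cell genes 43 rose and 2 fell (43 and 2 adjusted over the list alone), with a median of 4.87. Padi6 fell from 303 ± 45 to 42.8 ± 4.1, the maintenance methyltransferase gene Dnmt1 from 196 ± 4.2 to 25.6 ± 1.4 and Gm813 from 188 ± 31 to 4.89 ± 1.1, and 22 of 31 maternal genes fell while 5 rose (22 and 6 adjusted over the list alone). All 7 structural RNA genes rose (7 adjusted over the list alone), Rmrp from 9.89 ± 0.64 to 49.2 ± 11, as did 312 of 460 small and ribosomal RNA rows, with 9 lower. The share of small and ribosomal RNA in the FPKM sum was 40.4% to 42.4% in Late1c controls and 56.1% to 58.0% in Early2c controls. Also higher were Malat1, from 3.58 ± 1.2 to 27.7 ± 3.9, and Platr31, from 0.026 ± 0.045 to 5.96 ± 1.1. XLOC_026438 rose from 3.54 ± 0.85 to 432 ± 59. In all, 10439 of 13180 rows were called, 4413 higher and 6026 lower. For these controls scaling moved the changes by a median of 0.241 and gave 5800 higher and 4652 lower.

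The knockdown asked what changes in embryos injected with an ASO against LncR-3363. The locus XLOC_003363 carries this number and was at 0.162 ± 0.19 in Ctrl and 0.111 ± 0.22 in KD-1cell, below the filter. Whether it is this lncRNA is not stated in the sources used here, so the level of the target was not tested. The labels do not give the stage of the Ctrl embryos or whether they were injected. Effects of the injection therefore cannot be separated from those of the target. A small set of transcripts nearly vanished from KD-1cell embryos (n = 4 and 4). Ube2s (ENSMUSG00000060860.8, GRCm38 chromosome 7, 4794546 to 4812590), a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 32.2 ± 2.2 to 0.331 ± 0.15 (-5.32, adjusted p = 1.4e-08). E330021D16Rik (ENSMUSG00000045291.8, chromosome 6, 136400317 to 136415569), a protein-coding gene abundant in Ctrl, fell from 919 ± 27 to 33.8 ± 1.1 (-4.74, adjusted p = 3.3e-11). Asb8 fell by 4.41, the spindle gene Dlgap5 from 18.8 ± 0.78 to 0.501 ± 0.17, and Ccdc97, Hpcal1, Noct and Rab1b by 3.90, 3.79, 3.74 and 3.71. The transcripts of all 8 of these genes hold 1 or both of a pair of short sequences described below. Gm813, Bub1b and H1foo were higher in KD-1cell: Gm813 rose from 11.3 ± 3.8 to 56.6 ± 2.2 (2.34), the spindle checkpoint gene Bub1b from 11.5 ± 1.3 to 55.8 ± 11 (2.22, with 1 KD-1cell replicate apart from the other 3) and H1foo from 81.5 ± 7.3 to 240 ± 36 (1.54). Ooep, Npm2 and Padi6 each rose by 0.89, and 15 of 31 maternal genes rose and 2 fell (15 and 2 adjusted over the list alone; 12 and 4 with scaling). As a set the maternal genes had a camera adjusted p = 0.049, but an adjusted p = 0.295 with an estimated correlation and 0.161 with scaling.

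Among 45 2-cell genes in the knockdown 4 rose and 3 fell (2 and 0 adjusted over the list alone), and with scaling 2 rose and 11 fell. Duxf3 rose from 6.36 ± 1.6 to 15.4 ± 3.8 (1.20, adjusted p = 0.0014), and Tcstv1 fell from 13.4 ± 2.0 to 9.97 ± 0.98 (-0.40, adjusted p = 0.014), a call lost with no filter. Rmrp (ENSMUSG00000088088.1, the row meant throughout; another row of this symbol, ENSMUSG00000115420.1, fell by 2.74) fell by 1.16, 1 of 3 structural RNA genes of 7 to fall while 1 rose (3 and 1 adjusted over the list alone; 3 and 0 with scaling). Malat1 fell from 15.6 ± 0.45 to 11.1 ± 1.9 and Platr30 by 0.74. Of 8 snoRNA host genes 2 fell (0 adjusted over the list alone; 4 with scaling), of 11 blastocyst genes 4 rose (4 adjusted over the list alone; with scaling 1 rose and 1 fell), of 7 p53 and damage genes 1 rose and 1 fell (1 and 0 adjusted over the list alone; 1 and 2 with scaling), and of 11 housekeeping genes 3 rose, Ubb by 0.93, and 2 fell (3 and 2 adjusted over the list alone; 2 and 2 with scaling). XLOC_011428 fell from 8.74 ± 0.7 to 0.674 ± 0.36. In all, 5018 of 11492 rows were called, 3420 higher and 1598 lower, and at 2-fold or more 340 were higher and 520 lower. In the knockdown scaling moved the changes by a median of -0.133 and gave 2273 higher and 2437 lower. Small and ribosomal RNA took 41.1% to 47% of the FPKM sum in KD-1cell and 45.8% to 52.7% in Ctrl. Protein-coding genes took 42.7% to 47.7% and 36% to 41.6%. Of 337 small and ribosomal RNA rows 66 fell and 3 rose.

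Gene sets defined in the stage series share no library with the knockdown. In KD-1cell the 2576 genes that rise from zygote to E2-cell were lower than other genes (median -0.22, camera adjusted p = 2.55e-22, and adjusted p = 0.0441 with an estimated correlation). The 3147 genes that fall at that step were higher (median 0.45, camera adjusted p = 2.55e-22, and adjusted p = 0.00183 with an estimated correlation). The 258 genes lower from MII to zygote were also higher (adjusted p = 0.0293, and 0.0403 as an adjusted p with an estimated correlation). The 2-cell genes were lower as a set (camera adjusted p = 0.038) but had an adjusted p = 0.585 with an estimated correlation. The lists of snoRNA hosts, structural RNAs, blastocyst, housekeeping and p53 genes had camera adjusted p-values of 0.103, 0.103, 0.194, 0.938 and 0.887. Unlike camera, fry does not compare a set with other rows, so a shift of all rows also counts. With fry the adjusted p-values of these lists were 0.0176, 0.175, 0.000767, 0.0587 and 0.24. For the 2-cell and the maternal genes fry gave 0.543 and 0.000204, and for the genes that rise and fall from zygote to E2-cell 0.000802 and 1.07e-06.

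**Figure D2:**
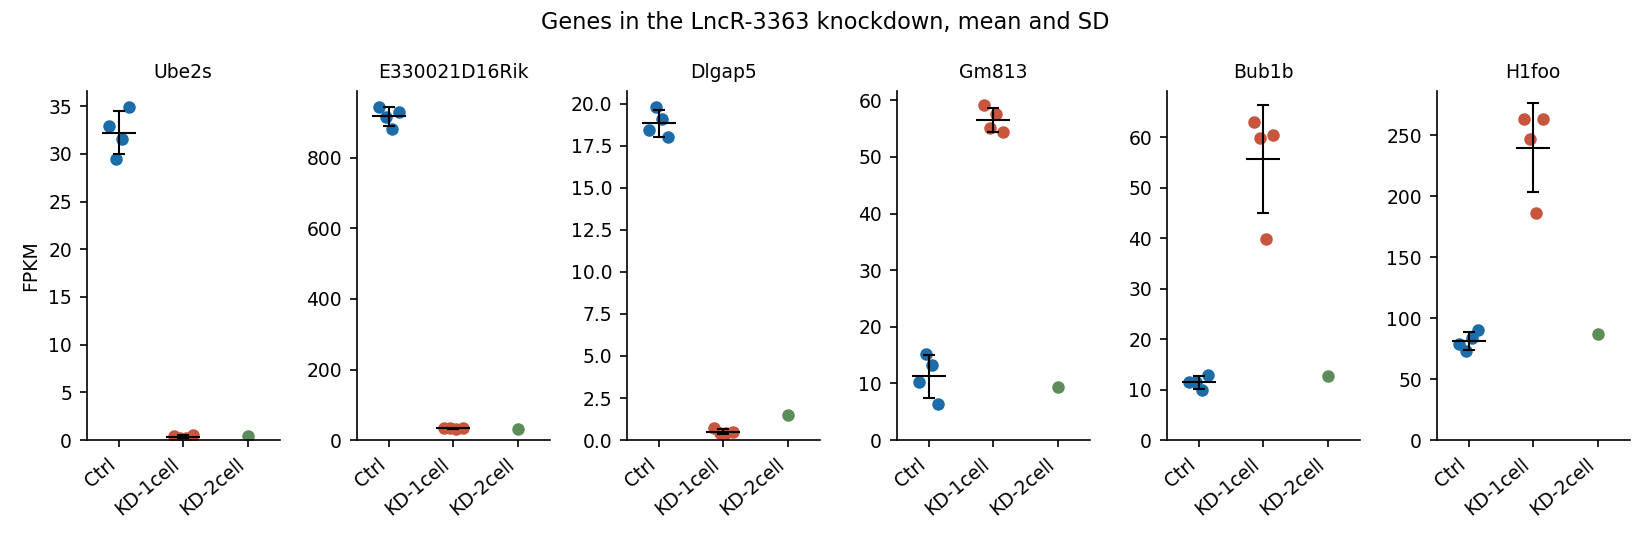
FPKM of 6 named genes in Ctrl, KD-1cell and the single KD-2cell sample of the LncR-3363 experiment; points are samples, and bars are the mean and SD of 4 samples for Ctrl and KD-1cell. Ube2s falls from 32.2 to 0.331, and H1foo, at 240 in KD-1cell, is at 86.9 in KD-2cell and 81.5 in Ctrl.

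The transcripts lowest in the knockdown were searched for shared sequences, a comparison chosen after the values were seen. Of 88 transcripts that fell by more than 2 on the log2 scale, 27 (30.7%) hold CTGGACGG, against 186 of 6987 others (2.66%), which is 11.5 times as frequent. Its reverse complement CCGTCCAG is in 1 of the 88 and in 222 of the others. Of the 61 without the first sequence 20 hold GACTGGAC, against 341 of 6801. Both sequences were chosen on these transcripts, so the frequencies among them are no test. With the sequence chosen in 1 random part of the transcripts and counted in the other, the median Fisher's exact p over 20 divisions was 3.7e-08. CTGGACGG was chosen in 8 of these divisions. In the others the choice was GACTGGAC, ACTGGACG, TGGACGGC or AGACTGGA, which all overlap CTGGACGG when shifted along it. Some lower genes with the sequence have related names, such as Lrp1, Lrp5 and Lrp6. If such genes are alike in sequence, they can fall in both random parts, and Fisher's exact p then overstates the evidence. Whether they are alike was not tested. Over all 307 transcripts with CTGGACGG the median change was -0.29, against 0.12 for 7391 with neither it nor its reverse complement. Transcripts on which the sequence was chosen are among them, so this shift is in part fixed by the choice. In the Early2c knockout the 307 had a median of 0.09.

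**Figure D3:**
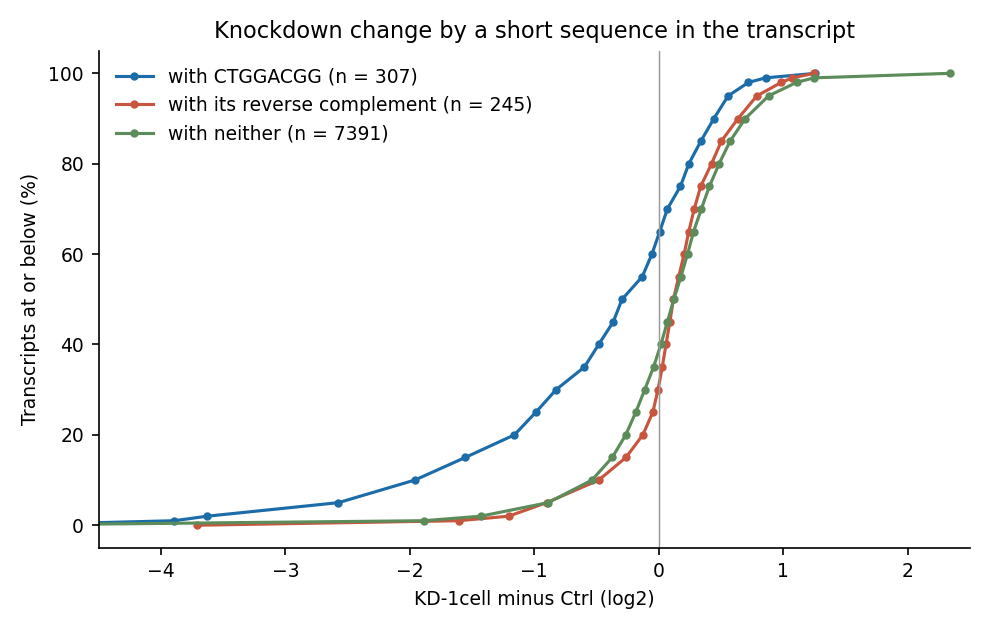
Cumulative percent of transcripts against the log2 change of KD-1cell over Ctrl, for 307 transcripts with CTGGACGG, 245 with its reverse complement and 7391 with neither; each line is 1 group of transcripts. The line of the first group lies to the left of the others, with a median of -0.29 against 0.12 and 0.12. The sequence was chosen on transcripts shown here, so this shift is in part fixed by the choice.

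The MT2Mm knockout asked which transcripts depend on this repeat. An injection is listed for the knockout groups and not for their controls, so effects of injection and target cannot be told apart. At Late1c the knockout embryos were close to their controls: 15 of 13180 rows were called, 6 higher and 9 lower, against 1108 at an unadjusted p under 0.05. The deubiquitinase genes Usp17lc, from 1.37 ± 0.5 to 0.361 ± 0.069 (adjusted p = 0.04), and Usp17ld, from 0.668 ± 0.031 to 0.207 ± 0.098 (adjusted p = 0.042), members of a family with near-identical copies, were the 2 of 46 2-cell genes that fell (6 adjusted over the list alone). The adhesion gene Cdh1 rose from 34.9 ± 1.2 to 44.5 ± 0.32 and Lsm14b, an RNA granule gene, from 190 ± 7.4 to 247 ± 11. None of these calls survived scaling by the median of ratios, which left 0 rows called and 1068 at an unadjusted p under 0.05 with limma; leaving out any 1 of the 6 libraries left 0 to 4. At Late1c limma called 0 of 31 maternal genes (5 at an unadjusted p under 0.05), 0 of 11 snoRNA host genes (2), 0 of 8 p53 and damage genes (2), 0 of 7 structural RNA genes (0) and 0 of 12 housekeeping genes (0). As a set the 2-cell genes had a median of -0.11 (camera adjusted p = 3.37e-08, but adjusted p = 0.274 with an estimated correlation), and the 305 genes lower from MII to zygote were higher than others (camera adjusted p = 0.000279, adjusted p = 0.98 with an estimated correlation). With fry the adjusted p-values of these sets were 0.0512 and 0.8.

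At Early2c the knockout changed many transcripts, and the larger falls were mostly outside protein-coding genes. XLOC_027969 fell from 18.1 ± 2.7 to 2.3 ± 0.4 (-2.73, adjusted p = 5.7e-08); the position of XLOC loci is not given in the sources used here. Gm28826 (ENSMUSG00000101447.1, GRCm38 chromosome 1, 47153461 to 47189071), a long intergenic noncoding RNA, fell from 7.44 ± 0.95 to 1.54 ± 0.2 (-1.96, adjusted p = 2.1e-07), Gm47897 fell by 2.06 and the pseudogene Gm16038 by 3.11. Platr31 fell from 5.96 ± 1.1 to 1.67 ± 0.3 and Malat1 from 27.7 ± 3.9 to 15.5 ± 2.0. Among 2-cell genes 16 of 46 fell and 6 rose (16 and 6 adjusted over the list alone; with scaling 25 fell and 5 rose): Spz1 (ENSMUSG00000046957.5, chromosome 13, 92574636 to 92576172) went from 13.6 ± 0.31 to 4.35 ± 0.051 (-1.54), B020004J07Rik from 15.9 ± 0.61 to 7.02 ± 0.38 and Zscan4c from 67.9 ± 0.81 to 46.1 ± 0.58. Of 7 structural RNA genes 5 fell (6 adjusted over the list alone; 6 with scaling), Rmrp from 49.2 ± 11 to 16.3 ± 0.76 and Rpph1 from 626 ± 91 to 351 ± 35, and 6 of 11 snoRNA host genes fell (6 adjusted over the list alone), Zfas1 by 1.03 and Snhg8 by 0.79. All 3 oocyte lncRNAs fell (3 adjusted over the list alone), C86187 by 0.25. Small and ribosomal RNA took 51.0% to 52.8% of the FPKM sum in these knockout libraries and 56.1% to 58.0% in their controls.

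Some maternal genes rose in the Early2c knockout and others fell. Kpna2 (ENSMUSG00000018362.14, GRCm38 chromosome 11, 106988629 to 106999541), which encodes an importin of nuclear transport, rose from 59.3 ± 2.7 to 245 ± 19 (2.04, adjusted p = 2.5e-08), Ooep from 32.9 ± 3.8 to 89.3 ± 9.9 (1.43), Padi6 by 1.20 and Dnmt1 from 25.6 ± 1.4 to 40.7 ± 2.8. In all, 18 of 31 maternal genes rose and 5 fell (19 and 5 adjusted over the list alone; 11 and 7 with scaling). Of 15 blastocyst genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; 5 and 2 with scaling), Klf4 by 0.52 and Gata3 by 0.77. Among 8 p53 and damage genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; 2 and 2 with scaling), with Gtse1 from 8.78 ± 0.35 to 17.8 ± 1.7 and Bax from 1.54 ± 0.53 to 3.0 ± 0.4. Markers of other cell types rose as well: 2 of 2 cumulus and granulosa markers tested (2 adjusted over the list alone; 1 with scaling) and the 1 sperm marker (1 adjusted over the list alone; 0 with scaling). Of 12 housekeeping genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), Eef1a1 by 1.06, while with scaling 3 rose and 4 fell. In all, 6458 of 13180 rows were called, 4402 higher and 2056 lower. At 2-fold or more, 315 protein-coding genes were higher and 28 lower, 17 XLOC loci were higher and 322 lower, and 19 annotated lncRNAs were higher and 71 lower. At Early2c scaling moved the changes by a median of -0.144 and gave 3043 higher and 3586 lower.

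As sets at Early2c, the 2901 genes that rise from zygote to E2-cell were lower (median -0.16, camera adjusted p = 9.4e-29, adjusted p = 0.000449 with an estimated correlation). The 3715 genes that fall at that step were higher (median 0.38, camera adjusted p = 2.1e-21), with an adjusted p = 0.0786 under an estimated correlation. The 2-cell genes (0.00134), structural RNAs (0.00134), snoRNA hosts (0.00689), the genes lower from E2-cell to L2-cell (0.000979) and those lower from MII to zygote (0.0241) passed camera with these adjusted p-values. With an estimated correlation their adjusted p-values were 0.291, 0.217, 0.217, 0.273 and 0.626, and with fry 0.0103, 0.000968, 0.00197, 3.95e-05 and 0.000873. Maternal, blastocyst and p53 lists had camera adjusted p-values of 0.0718, 0.149 and 0.248, and fry adjusted p-values of 0.00183, 3.95e-05 and 6.62e-05. For the maternal list the camera adjusted p was 0.658 with an estimated correlation and 0.0458 with the replicate block. The list of 5 broadly expressed lncRNAs had a median of 0.03 and a mean of -0.08. The list of 5 pluripotency lncRNAs had a median of 0.08 and a mean of -0.35. Neither list passed camera (adjusted p = 0.478 and 0.219), and fry gave an adjusted p = 0.748 and 0.00658.

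The difference between the effects at the 2 stages was tested directly. Kpna2 (2.14, adjusted p = 8.5e-07), Ooep (1.56), Padi6 (1.29) and Npm2 (0.79) rose more at Early2c than at Late1c, and XLOC_027969 (-2.68, adjusted p = 2.5e-06), Gm28826 (-1.90) and Platr31 (-1.70) fell more. In Late1c controls Platr31 was at 0.026 ± 0.045, Gm28826 at 0.0222 ± 0.038 and XLOC_027969 at 0.026 ± 0.026, which leaves no room for a fall there. In all, 4913 rows differed, 3382 upward and 1531 downward. Scaling moved the differences by a median of -0.153 and gave 2287 upward and 2655 downward. The genes that rise from zygote to E2-cell had a lower difference (camera adjusted p = 4.82e-24, adjusted p = 0.000868 with an estimated correlation). For those that fall (6.09e-18), those lower from E2-cell to L2-cell (0.000524) and the structural RNAs (0.0106), the adjusted p-values with an estimated correlation were 0.122, 0.362 and 0.362. With fry they were 9.83e-05, 0.000266 and 0.0179. Of 31 maternal genes 13 differed upward and 2 downward (13 and 2 adjusted over the list alone; 9 and 6 with scaling), and of 46 2-cell genes 8 upward and 6 downward (8 and 5 adjusted over the list alone), which turned to 6 and 11 with scaling.

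**Figure D4:**
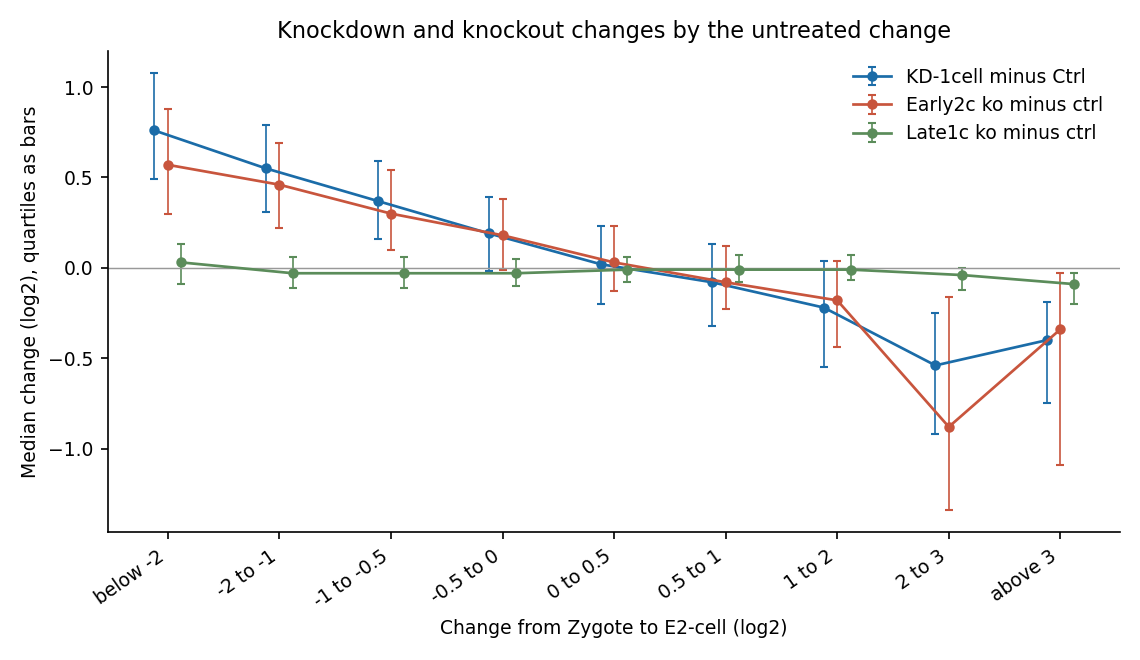
Median log2 change of the knockdown, the Late1c knockout and the Early2c knockout against the change from zygote to E2-cell in the stage series, in bins of genes; bars span the quartiles. Across 12606 genes, which are not independent replicates, the rank correlation was -0.57 for the Early2c knockout and -0.01 for the Late1c knockout, and across 11138 genes -0.59 for the knockdown. Genes that rise at this step can be near 0 at Late1c, with little room for a fall there.

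Among rows that rise by more than 1 on the log2 scale from zygote to E2-cell, the Early2c knockout separated protein-coding genes from other rows, in a comparison chosen after the values were seen. The median change was -0.13 for 755 protein-coding genes, -1.16 for 441 XLOC loci and -0.90 for 112 annotated lncRNAs. Of these, 14 protein-coding genes (1.85%), 261 XLOC loci (59.2%) and 48 annotated lncRNAs (42.9%) were below -1. In the knockdown the medians were -0.19, -0.71 and -0.51, and in the Late1c knockout -0.02, -0.05 and -0.03. Rows chosen for this rise can be near 0 at Late1c, which leaves little room for a fall there. The 20-base sequence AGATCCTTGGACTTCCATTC is in 36 of 154 transcripts lower in the Early2c knockout and in 16 of 7375 others, the transcripts on which it was chosen. With a sequence chosen in 1 random part of the transcripts and counted in the other, Fisher's exact p was between 5.8e-36 and 1.3e-17 in 20 divisions, in which the sequence chosen was not always this one. Its reverse complement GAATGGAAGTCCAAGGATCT is in 0 and 2. Of the 77 transcripts with the sequence 73 carry it within their first 150 bases. These include small RNAs of 120 or 121 bases, such as Gm22862 and Gm22468 (position 95), which cannot hold it further along. Some of the 77 have equal length and position of the sequence, such as Gm48829, Gm47404 and Gm47357 (2705 bases, position 54). If these are copies of a family, they can fall in both random parts, and Fisher's exact p then overstates the evidence. Whether they are copies was not tested.

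**Figure D5:**
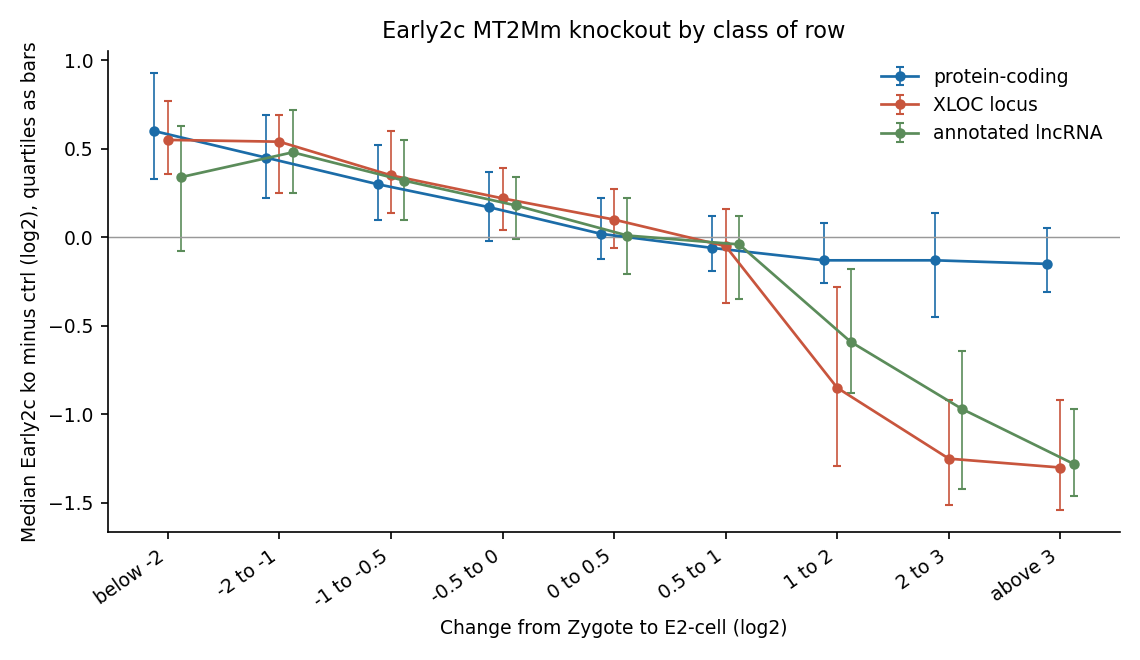
Median log2 change of Early2c knockout over control for protein-coding genes, annotated lncRNAs and XLOC loci, against the change from zygote to E2-cell in bins; points are medians per bin and bars span the quartiles. Among rows that rise by more than 1, the medians are -0.13, -0.90 and -1.16.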

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

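In this part the test of the difference between the knockout effects at the 2 stages was planned, and the tests of the 3 patterns, the splits of the samples and the comparison of KD-2cell were chosen only after the results were seen. The effects of the MT2Mm knockout differed between Early2c and Late1c in 4913 rows. Of 100 splits of the samples 3 gave as many, the real one included, which is under 0.05, and the highest of the others gave 5549. The 10 splits that kept the Early2c grouping, with any grouping of the Late1c samples, gave 3890 to 5549. No other split gave more than 4, so the count follows the Early2c grouping. The share under 0.05 therefore does not show that the effects differ between the stages. For the knockdown, 1 of 35 splits gave as many as the real 5018 rows, the real one, and the highest of the others gave 1. That share is under 0.05, but the splits were chosen after the count was seen. They do not tell what separates the groups, such as target, stage or injection. For Late1c (real value 15, highest other 3), Early2c (6458 and 3) and the controls of both stages (10439 and 1), 1 of 10 splits gave as many, the real one, and 10 splits are too few for a share under 0.05.

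The single KD-2cell sample, which is outside the knockdown comparison, was set against 2 of the 4 Ctrl samples and KD-1cell against the other 2, in the 6 possible ways. Of rows changed 2-fold or more in KD-1cell, 76.7% to 79.3% moved the same way in KD-2cell, by a median ratio of 0.23 to 0.27. When a Ctrl sample took its place the share was 44.8% to 55.1%. The 2 Ctrl samples of each way gave mirrored values, so this range lies around an even split by construction. It does not show what an independent sample would give. A sample far from the other 3 of its group was seen in 4 of 74 groups and genes tested, where chance gives about 1 in 20. The gap of the far sample, as a share of the range, was 0.868 for Bub1b and 0.866 for Rab1b in KD-1cell, and for Tcstv1 it was 0.844 in Ctrl and 0.947 in KD-1cell, against a critical value of 0.829.

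In the Early2c knockout, rows outside protein-coding genes that normally rise from zygote to E2-cell fell further than protein-coding ones. Lower recovery of RNA from XLOC loci in the knockout libraries is argued against by XLOC loci that do not rise. Their median difference was -0.04 (-0.08 to -0.02, 839 pairs) from protein-coding genes matched for level and for their changes at both 2-cell steps. Small and ribosomal RNA was not matched this way. Of its 460 rows 86 fell and 13 rose, so lower recovery of that class stays open. Slower development or earlier sampling stays open. Among rows that rise, XLOC loci lay below such matched genes by a median of -0.92 (-1.01 to -0.84, 440 pairs). In the knockdown, where MT2Mm was not targeted, they also lay below, by -0.46 (-0.53 to -0.39, 372 pairs), so matched rows need not move alike under a delay. The intervals of these differences resample pairs of rows and do not measure the spread between embryos. A candidate explanation is that the knockout acts on transcripts that start in a shared element: with a sequence chosen in 1 random part of the transcripts, the rising lncRNAs of the other part that hold it differed from those without it by a median of -0.54 (-0.78 to -0.31 in 20 divisions), but lncRNAs without it also fell and 21 protein-coding genes with the 20-base sequence had a median of -0.26, so its role cannot be told apart from the larger normal rise of lncRNAs that carry it (3.08 against 2.35). Possible copies of a family were not kept in the same part. Whether the sequence belongs to MT2Mm was not tested, since no repeat library was used here.

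Transcripts far lower in the knockdown share a short sequence. GC content or transcript length is argued against by transcripts matched for length, GC content and level that were not lower: in 0 of 20 random divisions of these into 2 equal parts was the sequence chosen in 1 part enriched in the other (Fisher's exact p under 0.001). Slower development is argued against by the normal change of the 27 lower transcripts with the sequence from zygote to E2-cell, with a median of 0.22 and an upper quartile of 0.75, while their median in the knockdown was -2.85. Whether these RNAs were lost because they match the injected ASO in part stays open: in the lower transcripts the chosen sequence was enriched in 18 of 20, but so it was in 20 of 20 for the lowest transcripts of the Early2c knockout, which received no ASO, so the test shows a shared sequence and not its cause. The sequence of the ASO is not given in the sources used here, and how much of the wider change in KD-1cell follows from loss of Ube2s, Dlgap5 and the others was not tested.

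In the knockdown and in the Early2c knockout, genes that fall from zygote to E2-cell were higher and genes that rise were lower. Scaling of the FPKM values shifts all genes of a library alike and cannot open the gap of 0.55 (0.53 to 0.57) between the medians of these groups in the Early2c knockout. This interval, and that of the knockdown gap below, resamples genes and does not measure the spread between embryos. A difference of the whole step from zygote to E2-cell between treated and control embryos is argued against by rows that rise by more than 3 at that step, with a median of -0.40 in the knockdown (quartiles -0.75 and -0.19) and -0.34 in the Early2c knockout (-1.09 and -0.03). Slower development or earlier sampling by less than this step is consistent with the gap in the Early2c knockout and the gap of 0.67 (0.65 to 0.69) in the knockdown, although failed activation and failed clearance at an unchanged pace would give the same. For the knockdown, Ctrl embryos collected later than KD-1cell by less than this step would also give the rank correlation of -0.59, and since the labels do not state the stage of Ctrl these cannot be told apart; in the single KD-2cell sample, which excludes nothing, the gap was 0.13 and the correlation -0.21.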

How the results depend on the processing

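The fits on replicates of a shared tag and the count without rows holding the sequence found in the knockdown were chosen after seeing the data; the other alternatives were chosen before the data were examined. Counts of called rows stayed within 1.5 times under every alternative run for the steps from zygote to 4-cell, morula to blastocyst, the knockdown, the Early2c knockout, the difference of effects and the controls of both stages. For the knockdown they were 5057 with KD-2cell as an added group and 4772 without the rows that hold the sequence.

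With each replicate left out in turn, called rows ranged from 371 to 5008 for zygote over MII, 6611 to 9578 for E2-cell over zygote, 12129 to 12332 for L2-cell over E2-cell, 9041 to 9796 for 4-cell over L2-cell, 4410 to 5194 for 8-cell over 4-cell, 2423 to 2990 for morula over 8-cell and 5248 to 6031 for blastocyst over morula. They ranged from 2579 to 3359 for 17 over 14 hours, 905 to 1188 for 20 over 17 hours, 4181 to 4751 for the knockdown, 0 to 4 for the Late1c knockout, 5434 to 5874 for the Early2c knockout, 4145 to 5133 for the difference of effects and 9780 to 10183 for the controls. In the stage and time series this leaves a group with 1 sample, which is assumed to vary like the other groups. Most counts fell with fewer samples; the rises to 5008 and 9578 without zygote replicate 2 and to 5133 without Late1c control replicate 2 were not traced, and the cause was not tested.

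Zygote over MII gave 449 rows with a pseudocount of 0.1 FPKM and 276 with the replicate block, and 17 over 14 hours gave 2898 with no filter. The Late1c knockout gave 44 with a pseudocount of 0.1 FPKM, 0 with 1 FPKM, 2 with no filter, 0 with median-of-ratios scaling, 0 with the block and 3 in a fit of the 2 groups alone. Of the 18 set tests past the threshold 5 remained by number with an estimated correlation. The cause was not tested for these values, except that no filter raises the number of rows adjusted over.

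Of 248 named pairs of gene and comparison, 240 kept their direction and call under every alternative run, and 8 lost the call under at least 1. Of these 8, 7 are the genes of the Late1c knockout and 1 is Tcstv1 in the knockdown. None turned direction. Many of these genes were named for large and separated changes in the same data, so this share does not speak for all called rows. Scaling turned the majority of calls from higher to lower or the reverse for zygote over MII (425 higher, 310 lower), E2-cell over zygote, 4-cell over L2-cell, blastocyst over morula, 17 over 14 hours (2016 and 2525), the knockdown, the Early2c knockout, the difference of effects (2287 and 2655) and the controls. Counting the samples of added sequencing apart was not run, since the table has 1 column per replicate, nor was any setting for the level of LncR-3363, since its row is not known, nor the block for steps that involve the 4-cell stage, whose columns carry other numbers. Depth is unknown, so what it limits cannot be stated beyond the simulated recovery of changes.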

Other observations

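The correlation at the end of this part was chosen only after the results were seen. A few transcripts followed courses of their own through the stages. Malat1 was at 0.935 ± 0.12 in the zygote, 63.8 ± 4.2 at the 4-cell stage, 141 ± 29 in the morula and 328 ± 11 in the blastocyst. Dppa1 was at 4.75 ± 0.91 in the oocyte, was listed at 0 in the 8-cell embryo and morula, and reached 69.4 ± 3.9 in the blastocyst. Usp50 fell from 12.2 ± 0.8 at the 4-cell stage to 0.0921 ± 0.075 at the 8-cell stage and was back at 11.2 ± 0.39 in the morula. The methylation factor Uhrf1 rose from 6.79 ± 0.47 in the morula to 70.2 ± 5.4 in the blastocyst, and Gapdh from 1.71 ± 0.06 to 27.4 ± 1.8 with the glucose transporter gene Slc2a3 (13.7 ± 0.99 to 111 ± 4.7).

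Gm15446 and Gm46426 moved together. Both were high in the zygote (16.1 ± 3.8 and 11.7 ± 7.4) and at 17 hours (15.7 ± 2.3 and 16.6 ± 2.8), low in MII oocytes (0.927 ± 0.13 and 0.0285 ± 0.0072), at 20 hours (1.58 ± 0.094 and 0.245 ± 0.091) and in E2-cell embryos (1.03 ± 0.093 and 0.156 ± 0.093), and between these in Late1c controls (4.24 ± 0.72 and 3.88 ± 0.47). XLOC_000034 reached 20.5 ± 0.22 in the zygote and was listed at 0 in MII, E2-cell and L2-cell embryos and at 17 and 20 hours. Spp1, Krt18, Timp1 and Vim, higher at 20 hours than at 17 hours, were lower in Late1c controls than at 20 hours (Spp1 at 0.107 ± 0.09, Krt18 at 0.0607 ± 0.061, with Timp1 listed at 0 and Vim listed at 0), while Lgals1 was at 2.49 ± 0.016 at 20 hours and 0.0136 ± 0.024 in Late1c controls.

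In the single KD-2cell sample, without replicates, Ube2s was at 0.48 FPKM, near the 0.331 ± 0.15 of KD-1cell, and Dlgap5 at 1.49, between the 0.501 ± 0.17 of KD-1cell and the 18.8 ± 0.78 of Ctrl, while Gm813 was at 9.38, Bub1b at 12.8 and H1foo at 86.9, near those of Ctrl (11.3 ± 3.8, 11.5 ± 1.3 and 81.5 ± 7.3). In the Early2c knockout Gm813 rose as well, from 4.89 ± 1.1 to 22.7 ± 4.8, whereas H1foo was at 78 ± 1.2 against 98.9 ± 10 in controls and Bub1b at 12.1 ± 0.81 against 10.4 ± 0.56. Across 11396 genes, which are not independent replicates, the changes of the knockdown and of the Early2c knockout had a rank correlation of 0.57. Both treated groups were injected, and whether their controls were is not known here.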
